A study of Oryza sativa with 4 samples.

How the data were processed

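Shoot RNA of RDV-infected and mock-inoculated rice was compared directly on 2-colour Agilent oligonucleotide arrays, with 1 extract in Cy3 and the other in Cy5 on each array. RNA was purified with a column kit and amplified with a low-input linear amplification kit, per the labels' protocols. Images were quantified with Agilent Feature Extraction 8.1.1.1, per the submitters' processing notes. The background correction, dye normalization and filters are not given in the sources used here.

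The deposited table holds 1 log10 ratio per row and array, as the authors processed it. Base 10 was taken because Feature Extraction writes its log ratio in that base; the table does not name it. Ratios were divided by log10 of 2 to give log2 values. Each column lay near 0, with medians on the log10 scale of −0.000985 and 0.00455 for the arrays of pair 1, −0.000253 for pair 2 and 0.000971 for pair 3 over rows listed with a gene, so centring by the authors is likely but its method is unknown. An exact 0 was found in 2.92%, 2.11%, 2.75% and 2.28% of these rows and was taken as a ratio that was likely not measured, since the software is known to write 0 then; keeping it as a ratio of 1 was an alternative.

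The direction of the ratios is not stated. The infected extract was in Cy5 on 3 arrays and in Cy3 on the dye-swapped one, per the labels. Listed rows of that array correlated at 0.829 with its partner as deposited, whereas rows with no listed gene correlated at −0.874, so the swapped column was taken as already turned by the authors and no sign was changed here. Because Feature Extraction reports Cy5 over Cy3, the common direction is likely infected over mock. That basis is not proof, since turning the other 3 columns would look the same apart from a sign.

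Of 22575 rows, 17839 have 1 gene in the platform annotation, 21 have several and 4715 have none listed. Only listed rows were tested, because control spots could not be told from other unlisted rows, and rows with several genes were tested but never named. All 17839 gene identifiers were found in the RefSeq gene table of assembly ASM3414082v1, which was used for names and for the order of genes. The build behind the probes is not given in the sources used here, so no coordinates are printed. A name beyond a locus number was found for 2110 of 15798 genes (2411 rows), and several probes of 1 gene were kept apart. Of 1780 genes with several tested probes, 1402 had no call, 83 had all probes called in 1 direction and 2 had calls in opposite directions. The other 293 had a call on some of their probes only.

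The 2 arrays of pair 1 hold the same extracts and were averaged, giving n = 3 pairs. The labels say that the pairs came from separate sets of seedlings, each a pool of plants, so the spread is between pools. Probes with a value in at least 2 pairs were fitted with limma 3.58.1 (R 4.3.3), lmFit and eBayes with an intercept only, against a log2 ratio of 0. P-values were two-sided and adjusted by Benjamini-Hochberg over 17501 probes, with a threshold of 0.05. Errors are SDs over the pairs. All adjusted p-values of genes come from this fit.

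Gene lists were tested with limma's camera with a preset correlation of 0.01, on probes with all 3 pairs, adjusted over the lists of a family. Before the data were examined, 27 lists were fixed as word patterns, along with the alternatives, the tests and the rule for named genes. The annotation turned out to hold symbols and no descriptions, so 11 of these lists reached the minimum of 5 probes. The same themes, with control genes added, were therefore written again as rice gene symbols, 28 lists in all, after the annotation had been seen and before any fold change of a named gene was seen. List results are for symbol lists unless called word-matched. Word-matched lists other than those in the results had adjusted p-values of 0.0907 (photosystems), 0.159 (peroxidases and glutathione transferases), 0.299 (WRKY), 0.148 (RNA silencing), 0.426 (jasmonate and ethylene), 0.678 (auxin, cytokinin and brassinosteroid), 0.148 (diterpenoid phytoalexins) and 0.913 (root markers). Adjusted over the list alone, these had 2 falls for photosystems (1 over all probes), 5 rises and 3 falls for RNA silencing (3 rises over all probes) and 3 rises for diterpenoid phytoalexins (1 over all probes). The others had the same counts both ways: 1 rise and 4 falls for peroxidases and glutathione transferases, 1 rise each for WRKY and for jasmonate and ethylene, 5 rises and 8 falls for auxin, cytokinin and brassinosteroid, and none for root markers. Where the results give no count adjusted over the list alone, it equals the count over all probes. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other probes, so a fry p neither supports nor removes a camera call. None of the lists of either family passed with an estimated correlation. With 3 pairs this form of camera has few residual degrees of freedom and could hardly call a list. For pathogenesis-related proteins the estimate, −0.0597, lay below the preset, yet the unadjusted camera p went from 0.00101 to 0.0736. For diterpenoid phytoalexins the estimate was −0.0794, and this p went from 0.00221 to 0.0842. A call lost in this form therefore does not by itself show that correlation between genes removes a shift. The estimate lay above the preset for other lists: cell wall (0.0634 word-matched, 0.0511 symbols), lignin and phenylpropanoid synthesis (0.0582) and chlorophyll and carotenoid synthesis (0.072). For these lists, correlation between genes and the few degrees of freedom cannot be told apart as reasons for the lost call.

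Genes were named by a rule: the 10 largest rises and the 10 largest falls among probes with 1 named gene, past the threshold and with 1 sign on all 4 arrays, with 1 probe per gene, and in each list up to 3 such probes of the largest size, or else the probe with the smallest p. The control genes were summarised as a group. This gave 90 genes. In word-matched lists where no probe passed, the smallest p belonged to OsPCNA at 0.40 (adjusted p = 0.0437, but without 1 sign on all arrays), OsCP1 (LOC4327535) at 0.10, APG8C at 0.18, OsSUT2 at 0.21, OsGBSS1 at 0.31, GLUA-1 at 0.15 and OsPIP1;1 at 0.19. OsGBSS1, a starch synthase known as waxy, was matched to the cuticle list by its name alone.

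The fit was tested on simulated data with the spread of the real fit, 3 pairs and 17501 probes. With 200 changed probes, the share recovered was 0.554% at a log2 ratio of 0.5, 54.8% at 1 and 89.3% at 2, and with 3000 changed probes it was 64.0%, 92.7% and 98.7%. False calls were 5.76% and 4.20% of all calls. A list of 50 probes shifted by 0.3 was called in 20 of 20 runs, and 0 of 400 unshifted lists were called. Probes were drawn independently and without dye bias, so false calls among lists of correlated genes were not tested. Each simulated probe had 1 spread in all 3 pairs. In the real data the estimated array weights differed, at 1.99, 1.03 and 0.488 for pairs 1, 2 and 3, so these rates may not hold there.

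The alternatives were leaving out the dye-swapped array, entering 4 arrays singly with the pair as a random block or as if independent, a dye term, subtracting the dye bias of pair 1, re-centring, equal scale, array weights, robust eBayes, probes on all arrays, probes whose dye-swapped ratios differed by at most 1, each pair left out, other thresholds, an ordinary t statistic, log base 2, probes averaged per gene, estimated correlation, fry and random lists. The function that estimates the correlation of a random block gave no value with 4 arrays in 3 blocks. A pooled value of 0.162 was therefore computed from squared differences, those between the arrays of pair 1 against those between pairs 2 and 3. The former include dye bias and the latter are in 1 dye orientation, so the value may be too low. A low value brings this setting nearer to 4 independent arrays. List tests in that setting used the pre-ranked form of camera. Summaries and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.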

Results

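Rice seedlings of the cultivar Nipponbare were infected with Rice dwarf virus (RDV), a virus with a double-stranded RNA genome that leafhoppers carry between plants, and RNA from their shoots was compared with RNA from mock-inoculated seedlings. Seedlings aged 9 days met about 50 insects per pot of 10 plants. The insects carried the virus for the infected group and were free of it for the mock group, so feeding by leafhoppers was common to both. Leaves were harvested 9 days later, at an age of 18 days, and pooled over plants. There were 3 pairs of pooled extracts, 1 infected and 1 mock in each, and 4 arrays, because the extracts of pair 1 were hybridised a second time with the dyes exchanged. The question was which genes differ in RNA level between infected and mock shoots. The number of arrays limits the precision, and signal over background is unknown because no spot intensities were used here.

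Infected shoots likely held more RNA of the transporter OsPDR1, the pathogenesis-related protein PBZ1 and 3 chitinases than mock shoots, and less of the germin-like protein OsGER5, the lipid transfer protein LTP110-A and the glucan synthase OsCslF8. The signs rest on the dyes in the labels and on the usual red over green ratio of the scanner software; the value table does not state its direction, and the opposite reading would turn every sign below. It does not name its log base either; base 10 was taken, and base 2 would shrink every log2 ratio to its value times 0.301. Of 17501 probes tested, 1130 were higher and 1746 were lower in infected shoots at an adjusted p of 0.05 (limma, 3 pairs). Of these, 257 were at least 2-fold higher and 618 at least 2-fold lower. As a description without a test, 9816 of the 17248 probes with all 3 pairs had 1 sign in all of them (56.9%). Independent signs would give 25%. Pairs 2 and 3 were hybridised in 1 dye orientation, so dye bias common to them can raise this share without infection. Leaving out pair 1 reduced the calls to 134 higher and 391 lower, and leaving out pair 2 to 137 higher and 369 lower, while leaving out pair 3 raised them to 1401 higher and 1953 lower. An ordinary t statistic on each probe alone called 3 higher and 3 lower.

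Among genes with a name, the largest rise was that of OsPDR1 (LOC4346210), an ABC transporter of the pleiotropic drug resistance type, with a log2 ratio of 4.39 ± 0.59 (SD, n = 3 pairs; adjusted p = 0.00255). PBZ1 (LOC4352491), a pathogenesis-related protein of class 10 that is induced by probenazole, followed at 3.29 ± 0.23. The chitinases OsChia2b, OsChia1a and OsChia4a, enzymes that cut the chitin of fungal walls and insect cuticles, rose to log2 ratios of 2.58 ± 0.32, 2.53 ± 0.76 and 2.39 ± 0.44. OsASMT1 and OsASMT3, named for N-acetylserotonin methyltransferase, the last enzyme of melatonin synthesis, rose by 2.75 ± 0.93 and 2.41 ± 0.56. The ammonium transporter OsAMT3;2 stood at 2.59 ± 0.54, the lipoxygenase LOX1.1 at 2.47 ± 0.93, and the Argonaute protein OsAGO18, which binds small RNAs, at 2.34 ± 0.32. The adjusted p of these 10 genes lay between 0.00116 and 0.0224, and each was higher on 4 of 4 arrays, as the rule for naming required. OsAGO18 has another probe, at 0.16 ± 0.15 (adjusted p = 0.289), so its rise rests on 1 of its probes. Probes of gene families with similar members (chitinases, lipid transfer proteins, germin-like proteins, peroxidases) were not checked for signal from relatives, so the share of each member in these values is uncertain.

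The largest fall of a named gene was that of OsGER5 (LOC4345763), a germin-like protein of the cell wall space, at −5.04 ± 0.39 (adjusted p = 0.00116). A second germin-like gene, OsGER8, fell to −3.27 ± 0.06. LTP110-A, a lipid transfer protein, fell to −4.31 ± 0.16, and a peroxidase (LOC4339222) to −3.39 ± 0.25. 3 wall-related genes were among the 10 largest falls: OsAT15, of the acyltransferase family that adds hydroxycinnamates to grass cell walls, at −3.25 ± 0.26, OsCslF8, of the family that makes mixed-linkage glucan, at −3.08 ± 0.42, and OsPMEI8, a pectin methylesterase inhibitor, at −2.97 ± 0.20. The others were the acyltransferase OsTBT2 at −2.98 ± 0.21, the homeobox gene HOS66 at −2.76 ± 0.53 and the protein kinase OsNek4 at −2.34 ± 0.30. Genes without a name beyond a locus number moved further, down to −5.94 ± 0.22 for LOC4348123 and up to 4.70 ± 0.48 for LOC4324669.

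**Figure D1:**
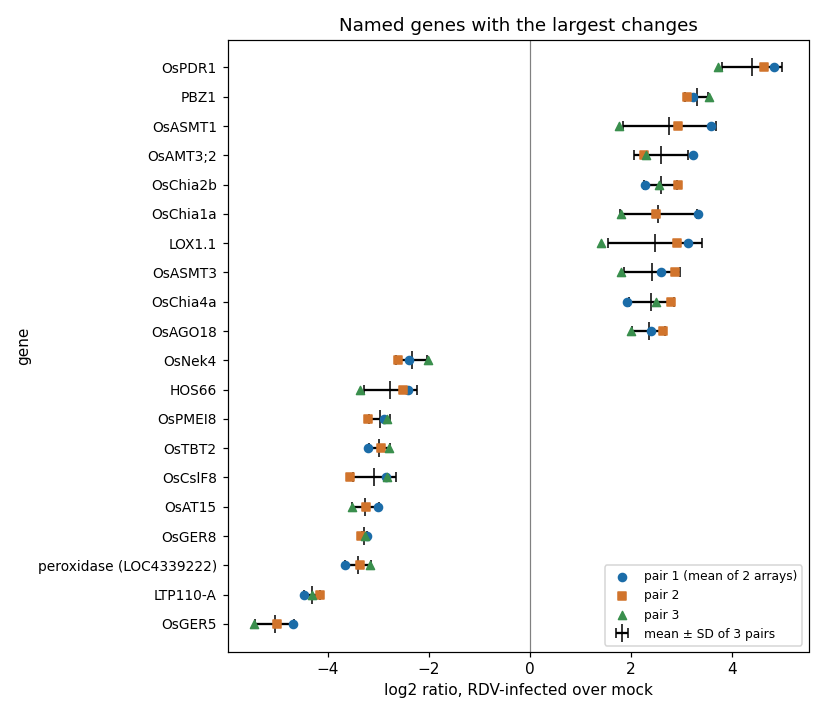
Log2 ratios of infected over mock shoots (x axis) for the 10 named genes with the largest rises and the 10 with the largest falls (y axis); symbols are the 3 pairs, and bars are the mean ± SD. All 3 pairs lie on 1 side of 0 for each gene, as the rule for naming required. The means run from −5.04 for OsGER5 to 4.39 for OsPDR1.

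Pathogenesis-related proteins were higher as a list. Of 14 probes written for this list as gene symbols, 5 rose, none fell and 9 did not pass, and adjusted over the list alone 7 rose. The fifth besides PBZ1 and the 3 chitinases above was the chitinase Cht11 at 1.31. The list had a median log2 ratio of 0.31 and passed limma's camera test at an adjusted p of 0.00941 over 28 lists. With an estimated correlation its adjusted p was 0.531, although the estimate, −0.0597, lay below the preset 0.01. The word-matched version of the list, with 8 probes, had 3 rises and did not pass (adjusted p = 0.0907). Germin-like proteins, lipid transfer proteins and peroxidases past the threshold were placed in other lists, so the counts here do not cover them. Of 8 OsGER genes 2 fell and none rose, and of 5 lipid transfer protein genes 4 fell and 1 rose. A peroxidase (LOC4339222) fell to −3.39 and another (LOC4344277) rose to 1.89. Enzymes of diterpenoid phytoalexins, the antimicrobial compounds of rice leaves, had 3 rises among 13 probes (adjusted over the list alone, 6) and an adjusted p of 0.0146, against an adjusted p of 0.531 with an estimated correlation. The members that rose were CYP71Z7 at 1.08 ± 0.35, CYP99A2 at 0.48 ± 0.17 and the diterpene synthase OsKS10, which was 2.01-fold higher. This list lost its call with a dye term for each probe (adjusted p = 0.055), with the dye bias subtracted (0.0845), without pair 2 (0.0629) and with the pair as a random block (0.195).

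Immune receptors and signalling genes did not shift as a list: 1 of 34 probes rose and 4 fell (adjusted p = 0.622), and the median of 0.08 and the mean of −0.03 differed in sign. The probe that rose belonged to OsWRKY62, a transcription factor of the defence response, at 0.63 ± 0.22. The falls included Os8N3, a sugar transporter that bacterial blight exploits, at −2.20 ± 0.60, and the transcription factor OsbHLH003 at −1.15 ± 0.48. Of 5 WRKY probes, OsWRKY62 alone passed (list adjusted p = 0.313). RNA silencing genes had 3 rises and no fall among 28 probes (adjusted over the list alone, 2 rises), and the list did not pass (adjusted p = 0.178). Besides OsAGO18, OsAGO1d rose to 0.73 ± 0.08 on 1 of its probes, with the other at −0.20 ± 0.08 (adjusted p = 0.145), and the Dicer-like gene OsDCL4 rose to 0.36 ± 0.06. Heat shock proteins and chaperones had 8 rises and 3 falls among 56 probes (adjusted over the list alone, 9 and 3), with a median of 0.19 (adjusted p = 0.0146, and adjusted p = 0.531 with an estimated correlation). CLPB1, a disaggregase, rose to 1.29 ± 0.46, the heat shock factor OsHsf-23 to 1.14 ± 0.54 and OsHsp18.0 to 1.03 ± 0.32 on 1 of its probes (the other at 0.19, adjusted p = 0.19), while a chaperonin (LOC4340394) fell to −0.99 ± 0.06. The word-matched heat shock list had 3 rises and 2 falls among 31 probes and an adjusted p of 0.884, and the symbol list lost its call with a dye term (adjusted p = 0.0844), with the dye bias subtracted (0.0731) and with the pair as a random block (0.164).

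Genes of cell wall synthesis and loosening were lower as a list, although most of their probes did not pass. Of 60 word-matched probes, the version fixed before the data were examined, 15 fell, 1 rose and 44 did not pass, and adjusted over the list alone 18 fell and 1 rose. It was the single list of the 11 tested word-matched lists to pass (adjusted p = 0.00479), and its adjusted p was 0.589 with an estimated correlation. The symbol version had 31 falls and 3 rises among 116 probes (adjusted over the list alone, 37 and 4), a median of −0.21 and an adjusted p of 0.00014, against an adjusted p of 0.531 with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other probes, gave adjusted p-values of 0.0742 and 0.0543 for these versions. OsCesA4, a cellulose synthase subunit of secondary walls, fell to −1.98 ± 0.31, and the expansin OsEXP16, of a family that loosens walls, to −1.27 ± 0.20. Cellulose synthase genes were singled out after their values were seen: 6 of 8 CesA genes fell on 8 of 13 probes, with OsCesA3 at −1.08, OsCesA8 at −1.06, OsCesA7 at −0.98 and OsCesA5 at −0.84. Enzymes of lignin and phenylpropanoid synthesis had 12 falls and 1 rise among 34 probes (adjusted over the list alone, 16 and 4), a median of −0.35 and an adjusted p of 0.0211, against an adjusted p of 0.608 with an estimated correlation. The laccases LAC4, LAC10 and LAC20, which couple lignin precursors, fell to −1.94 ± 0.61, −1.58 ± 0.19 and −1.44 ± 0.27. This list lost its call without the dye-swapped array (adjusted p = 0.0583) and with probes averaged per gene (0.0546). The wall, plastid and defence lists were written with prior knowledge of published work on this infection, likely including these arrays, so they are not independent evidence of direction.

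Enzymes of chlorophyll and carotenoid synthesis were lower as a list, with 9 falls and no rise among 29 probes (adjusted over the list alone, 12 falls and 1 rise) and a median of −0.21. The adjusted p was 0.000979, and it was 0.531 with an estimated correlation. PORA, a light-dependent protochlorophyllide reductase, fell to −1.67 ± 0.12, UPD1 to −1.33 ± 0.07, and CPX was 2.14-fold lower. Photosystem and light-harvesting genes had 3 falls and no rise among 17 probes and did not pass as a list (adjusted p = 0.0667); the falls were LP02 at −0.73 ± 0.07 (its other probe at −0.36, adjusted p = 0.136), NDH-M at −0.43 ± 0.10 and GOS5 at −0.38 ± 0.06. Calvin cycle and photorespiration genes had 4 falls and 1 rise among 15 probes (adjusted p = 0.417), including the glycolate oxidase OsGLO3 at −0.72 ± 0.25, GDCSH at −0.54 ± 0.10 and AldC-1 at −0.50 ± 0.15. AldC-1 was matched by its symbol alone, and whether this aldolase acts in the plastid was not checked. Plastid proteases, import and expression proteins went both ways, with 5 rises and 8 falls among 46 probes (list adjusted p = 0.201), and adjusted over the list alone 6 rose and 14 fell. The FtsH-type protease OsFTSH6 rose to 2.09 ± 0.14 and the Clp protein CLPD1 to 1.16 ± 0.40, and CL18 fell to −1.99 ± 0.07. Senescence and autophagy genes had 3 rises among 10 probes (adjusted p = 0.239): SGR, which starts chlorophyll breakdown, at 1.17 ± 0.54, OsNYC1, a chlorophyll b reductase, at 0.60 ± 0.07, and OsVPE1 at 0.56 ± 0.16.

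Peroxidases, glutathione transferases and redox enzymes had 13 falls and 2 rises among 42 probes (adjusted over the list alone, 14 and 3). The list lay close to the threshold (adjusted p = 0.0449, and adjusted p = 0.531 with an estimated correlation), and it passed in 6 of the 17 other camera settings with the preset correlation, where its adjusted p ran from 0.000572 to 0.0932. Its largest falls, OsGER5, the peroxidase LOC4339222 and OsGER8, are given above; germin-like proteins are not peroxidases, and some act as superoxide dismutases. The glutathione transferase GST-I fell to −1.27 ± 0.14, and another peroxidase (LOC4344277) rose to 1.89 ± 0.92.

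**Figure D2:**
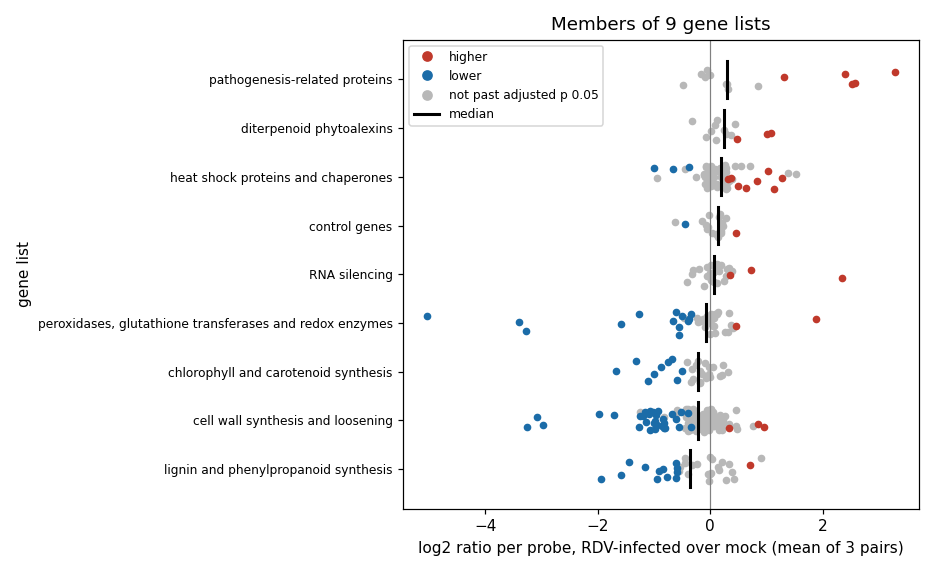
Log2 ratio of infected over mock shoots per probe (x axis, mean of 3 pairs) for 9 gene lists written as symbols (y axis): the 7 that passed the camera test, RNA silencing, and control genes. Colours mark probes past an adjusted p of 0.05, and black lines are list medians, from −0.35 for lignin and phenylpropanoid synthesis to 0.31 for pathogenesis-related proteins.

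Hormone genes moved in both directions without a shift of their lists. Of 109 probes for auxin, cytokinin and brassinosteroid response, 8 rose and 10 fell (adjusted p = 0.729). OsMGH3 and OsGH3-2, of the family that conjugates auxin to amino acids, rose to 2.10 ± 0.14 and 1.40 ± 0.14. OsDWARF, a brassinosteroid oxidase, fell to −1.45 ± 0.26, and the auxin response factor OsETTIN2 to −1.31 ± 0.18. Gibberellin genes had 3 falls and no rise among 16 probes (adjusted over the list alone, 5 falls and 1 rise, and list adjusted p = 0.257): OsCPS, which makes the first committed precursor of gibberellins, at −0.93 ± 0.20, GF14E at −0.49 ± 0.19 (its other probe at 0.05, adjusted p = 0.615) and CYP714C2 at −0.48 ± 0.20. GF14E was matched by its symbol or synonyms alone, and its role in gibberellin response was not checked. Jasmonate and ethylene genes had 2 rises and 1 fall among 55 probes (adjusted p = 0.258), the repressor OsJAZ7 at 0.91 ± 0.26, the lipoxygenase CM-LOX2 at 0.80 ± 0.05 and the ethylene-forming enzyme ACO1 at −0.97 ± 0.30.

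3 sucrose synthases fell, and ammonium transporters went both ways; neither metabolic list passed. Starch and sucrose metabolism had 10 falls and 3 rises among 50 probes (adjusted over the list alone, 11 and 4; list adjusted p = 0.502), led by OsSUS1 at −2.12 ± 0.20, OsSUS6 at −1.79 ± 0.34 (its other probe at −0.36, adjusted p = 0.261) and OsSUS5 at −1.25 ± 0.26. Amino acid and nitrogen metabolism had 5 rises and 1 fall among 32 probes (adjusted over the list alone, 8 and 4; list adjusted p = 0.622), led by OsAMT3;2, its relative OsAMT3;3 at 1.32 ± 0.64 and the urea transporter OsDUR3, which was 2.14-fold higher. The fall was that of another ammonium transporter, OsAMT2;3, at −0.38 (adjusted p = 0.0435), named after its value was seen. Cell cycle and histone genes had 17 falls and 4 rises among 100 probes (adjusted over the list alone, 20 and 4; list adjusted p = 0.324), with the cyclin CYCP2-1 at −1.86 ± 0.43, the tubulin OSTB-34 at −1.46 ± 0.44 on 1 of its probes (the other at 0.01, adjusted p = 0.967) and the kinesin KIN14F at −1.37 ± 0.29. Cytosolic ribosomal proteins had no call among 20 probes, with the smallest p for QM1 at 0.27 ± 0.07 (adjusted p = 0.0767). Ubiquitin and proteasome genes had 1 fall among 50 probes, OsUBC5a at −0.44 ± 0.17, and none adjusted over the list alone. The medians of both lists, −0.02 in each, lay below 0 while the test pointed above it (adjusted p = 0.748 and 0.962). Protease inhibitors and lectins had 1 rise among 11 probes, OC-XII at 0.40 ± 0.01 (list adjusted p = 0.258).

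Markers of other tissues were measured because a pooled shoot can hold more or less of each. Epidermis and cuticle markers had 7 falls and 2 rises among 17 probes (adjusted over the list alone, 8 and 3; list adjusted p = 0.11), with LTP110-A, LTP2-A at −1.86 ± 0.10 and LTP2-B at −1.57 ± 0.04 in the lead. These falls stand beside those of the wall lists. Phloem and vascular markers had 1 fall among 13 probes, Os8N3 (list adjusted p = 0.814, median 0.04 and mean −0.06). Seed and aleurone markers had 1 rise, ALK at 0.85 ± 0.19 (its other probe at −0.33, adjusted p = 0.124), and 1 fall, RA14 at −0.49 ± 0.20, among 15 probes (list adjusted p = 0.502). Root and iron acquisition markers had 6 rises and 4 falls among 56 probes (list adjusted p = 0.825, median −0.06 and mean 0.04), with OsNAS2, which makes the metal carrier nicotianamine, at 2.17 ± 0.56, the potassium transporter OsHAK1 at 1.72 ± 0.26 and the aquaporin OsTIP2;2 at −1.17 ± 0.30. Control genes (actin, ubiquitin, eIF-4A, GAPDH and elongation factor 1-alpha) had a median of 0.14 over 19 probes, with 1 rise, GAPC at 0.46 ± 0.09 (its other probe at 0.29, adjusted p = 0.0709), and 1 fall, OsUBC5a, and neither passed when adjusted over the list alone.

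The ratios of the 4 arrays were positively correlated, least so for pair 3. Across 17094 probes with a value on all arrays, the 2 arrays of pair 1 had a Pearson correlation of 0.829. Between arrays of different pairs it was 0.866 for pair 1 and pair 2 in the same dye orientation, 0.771 for the swapped array and pair 2, 0.696 and 0.625 for the arrays of pair 1 and pair 3, and 0.658 for pair 2 and pair 3. Probes are not independent replicates, so no p is given. Dye bias, taken as the part of pair 1 that turned with the dyes, had an SD of 0.17 on the log2 scale. Its correlation with the ratios of pair 2 was 0.221 and with those of pair 3 was 0.168, pairs that were hybridised in 1 orientation only. With the dye effect of each probe as a covariate, 1315 probes were higher and 1812 lower, and 2532 of the main calls were shared, all in the same direction.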

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

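All tests in this part were chosen after the values had been seen. Signals outside the tested probes were found in the 4715 rows with no listed gene. Of these, 400 were over 10-fold on all 4 arrays, and 397 of them had the opposite sign on the dye-swapped array. Their median log2 ratios were −6.46, −6.04 and −5.70 on the arrays with infected RNA in Cy5 and 5.96 on the swapped one. Of the 23 listed rows over 10-fold on all arrays, 0 turned with the dyes. Spots that bind 1 dye, with the swapped column turned by the authors, are a candidate explanation that was not tested independently: the share of 99.2% that turned is the observation it was drawn from. Dyes that were not in fact exchanged on the second array are argued against by the same 397 rows, since those rows would then keep their sign. No biological explanation was tested.

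Among 4350 such rows with enough values, 86 were called higher and 113 lower when they were fitted together with the listed probes (limma, adjusted p 0.05). At least 2-fold changes made up 40 and 48 of these. They carry no gene name here.

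The excess of falls over rises among large changes was weighed against dye bias and centring. In pair 1, where the dye effect cancels in the mean of both orientations, 748 probes were at least 2-fold lower and 360 higher, 2.08 falls per rise. That argues against the dye bias of the pairs in 1 orientation as the whole cause. A shift of the centre moves both tails alike, yet the 1st percentile lay farther from the median than the 99th in each pair, by 1.36, 1.39 and 1.27 times. The smallest of these, 1.27, argues against a mere shift of the centre as the cause. Infection itself, the unknown dye normalization and a treatment of dim spots by the scanner software stay open. No intensities were used here, and none of these was tested.

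The 3 pairs allow 4 sign patterns when infected and mock are exchanged within pairs, the real one included, too few for a share under 0.05. The real pattern gave 2876 calls and the highest other 0 (limma, with 441 at an unadjusted p under 0.05 against 5844 in the real pattern); 1 of the 4 patterns was as large. For symbol lists the real pattern gave 7 and the highest other 3, and 1 of 4 was as large. For word-matched lists the real pattern gave 1 and the highest other 3, and 3 of 4 were as large.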

How the results depend on the processing

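The direction of the 83 named genes past the threshold was the same wherever they were fitted in 16 other settings: 81 of them with probes left out whose dye-swapped ratios differed by over 1, and 83 in the others. All but OsPCNA had been named for having 1 sign on all 4 arrays, so most of these settings could not turn that direction. Of these settings, 2 (exact 0 kept, unlisted rows included) were chosen after seeing the data. In settings with all 3 pairs, 65 to 83 of the 83 genes stayed past the threshold, and without 1 pair 34 to 78 did. OsCP1 (LOC4327535), not past the threshold at 0.10, stood between −0.0203 and 0.32 when 1 pair was left out. The count of higher probes was 1706 with the pair as a random block, 1924 with 4 arrays as if independent and 1897 with array weights, and in each case the lower count moved by less than 1.5 times. By construction, entering 4 arrays singly adds the technical repeat of pair 1 as a further value per probe. The array weights were 1.99, 1.03 and 0.488 for pairs 1, 2 and 3, so pair 3 counted least. How far this accounts for the added calls was not tested. Leaving out 1 pair gave 134 to 1401 higher and 369 to 1953 lower probes, of which 133 to 330 and 365 to 710 were at least 2-fold. The low ends of the main counts come from leaving out pair 1 or pair 2 and the high ends from leaving out pair 3, all with the same number of pairs; the cause was not tested. A t statistic on each probe alone gave 3 and 3, a threshold of 0.01 gave 216 higher and 646 lower, one of 0.10 gave 2043 higher, and a 2-fold minimum gave 257 and 618, as their construction implies. Read as log2, the values left 10 probes at least 2-fold higher and 28 lower among the same calls. The share of falls among calls was 60.7%, and in other fits at the same threshold it ran from 54.7% (independent arrays) to 74.5% (without pair 1), apart from the t statistic, with 3 of 6; the cause was not tested. Word-matched lists past the threshold numbered 1 in the main setting, 2 without the swapped array, with the random block, with independent arrays, with the dye term, with the dye bias subtracted and with fry (another question), 1 to 5 without 1 pair, and 0 with an estimated correlation; the cause was not tested. By random lists the count was 4, on a looser measure: the percentile of the list median, not adjusted over the lists. Symbol lists numbered 7, and 5 to 10 elsewhere except 0 with an estimated correlation, with 8 by random lists on that looser measure. Spearman correlations were 0.622 within pair 1 and 0.570 on average between pairs, against Pearson values of 0.829 and 0.723, and leaving out 1 pair gave Pearson values of 0.658 to 0.819 between pairs. The average hides the dye orientation. In 1 orientation the Spearman values were 0.770 (pairs 1 and 2), 0.601 (pairs 1 and 3) and 0.507 (pairs 2 and 3). The swapped array had 0.524 with pair 2 and 0.448 with pair 3. Pairs 1 and 2 in 1 orientation thus agreed more than the 2 arrays of pair 1. On probes past the threshold the correlation of dye bias with pair 3 was 0.225 against 0.168; the cause was not tested. Signal over background is unknown, so how far dim spots limit these counts could not be seen.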

Other observations

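The groups of genes in this part were chosen after the data had been seen, and what each test of neighbouring genes would show was written down only after its result was known. Named genes were grouped by the stem of their symbol, and 115 stems with at least 5 probes were tested with camera. The stems CesA (cellulose synthase, adjusted p = 0.0111) and CslF (mixed-linkage glucan synthase, adjusted p = 0.0362) passed, both lower, with medians of −0.84 and −0.98. With an estimated correlation their adjusted p was 0.997. Among CslF genes, 3 of 4 fell: OsCslF8, OsCslF6 at −1.20 on 1 of its probes, with the other at −0.39 (adjusted p = 0.0818), and OsCslF2 at −0.98. Lipid transfer proteins had 4 falls and 1 rise among 5 genes (adjusted p = 0.0568). Transporters of the pleiotropic drug resistance type had 4 rises and 1 fall among 13 probes (adjusted p = 0.205); besides OsPDR1, OsPDR9 rose to 1.88, OsPDR5 to 0.89 and OsPDR16 to 0.56 (without 1 sign on all 4 arrays), and OsPDR12 fell to −0.56 on 1 of its probes.

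Neighbouring genes were called in the same direction more often than random placement gave. Of 8859 pairs of adjacent tested genes, 197 were called in the same direction, against a mean of 140.2 in 10000 random placements (permutation p = 0.0001, the smallest they can give). The excess was 1.79 times for pairs that both rose (75 pairs, with at most 67 in a random placement, permutation p = 0.0001). It was weaker, 1.24 times, for pairs that both fell (122 pairs, with up to 134 in a random placement, permutation p = 0.008). Over both kinds it was 1.41 times for adjacent genes, 1.15, 1.07, 1.03 and 0.977 times for genes 2, 3, 5 and 10 places apart, and 1.12 times for genes 20 places apart. Adjacent pairs called in opposite directions numbered 104, against a mean of 128.4, or 0.810 times. Placement by chance of pairs called in 1 direction is thus argued against. Whether probes that take up RNA of a similar neighbour account for part of the excess is open. Of 10 pairs called in 1 direction with names on both sides, 6 shared a symbol stem, among them OsChia2b with OsChia4a, LTP110-A with LTP2-A and OsCslF8 with OsCslF2. The share among other adjacent named pairs was not computed, so this count cannot decide it. Because 10 of 197 pairs have both names and no probe sequences were used here, shared signal and joint regulation of duplicated genes cannot be told apart.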
